A study of Canis lupus familiaris with 8 samples.

How the data were processed

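Small RNA libraries were made from RNA of vesicles (exosomes) in cell-free, serum-free conditioned medium of dog mammary cells. Per the labels, 5 samples came from canine mammary tumour (CMT) cell lines of carcinoma origin and 3 from normal canine mammary epithelial cells (CMEC). The medium of the first 24 hours was discarded, that of the following 48 hours was collected on day 3, and RNA was extracted from 5 mL with a kit for exosomal RNA. Per the labels, 500 ng of RNA entered each library, single reads of 50 bases were taken, and a worm miRNA was spiked in at 10 pM. The spike-in was not analysed here, because the table used here has no row for it.

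The deposited table held 1 normalised signal per mature miRNA locus and library for 511 loci, linear and with a lowest value of exactly 1 in each library. The submitters' processing notes name the genome build canFam3. The aligner, the counting program, the annotation version and the normalisation method are not given in the sources used here. The values themselves showed how the deposited signal had been scaled. Above the floor of 1, between 99.0% and 100% of the values in a library were whole multiples of 1 step per library, within a tolerance of 0.05 steps. The values were therefore read as reads divided by 1 factor per library, with results below 1 set to 1. That reading was taken from the values and is not recorded in a label. The step times the median-of-ratios factor of the recovered reads would be equal in all libraries if the authors had used that scaling over these loci. It was 4.50 in CMT-27, 0.496 in CMEC2 and between 0.766 and 1.20 in the other libraries.

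For 45 mature miRNAs with several loci, the locus with the highest mean was kept, which merged 59 loci and left 452 miRNAs. This choice was made after the table was seen and before any model was fitted. The recovered reads, 1 locus per miRNA, numbered 1405893 in CMT-27, 845889 in CMT-28, 81138 in CMT-12, 1044754 in CMT-47, 540306 in CMT-119, 404290 in CMEC1, 85906 in CMEC2 and 346585 in CMEC3. These reads cover the listed loci only, and total reads per library were not counted here. Depth below means recovered reads and may differ from sequencing depth, which the labels give as about the same for each library. One read was worth 2.32 in CMT-12 and 2.83 in CMEC2, against 0.386 to 1.39 in the other libraries. Values under about 8.5, the worth of 3 reads in CMEC2, therefore rested on at most 3 reads in CMEC2. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

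Groups were taken from the labels. The tumour lines are separate lines. The normal samples are numbered 1 to 3 and the labels do not say whether they came from separate dogs, so p-values measure the spread between these samples. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom of any pair was 92.7, between CMEC2 and CMEC3.

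miRNAs above the floor in at least 3 of the 8 libraries were tested, 193 in all. log2(value + 1) was fitted with limma 3.58.1 (eBayes with an intensity trend) in R 4.3.3, coded as CMT minus CMEC, with a Benjamini-Hochberg threshold of 0.05. Fold changes on this scale understate the change of low miRNAs. Fixed lists of miRNA families, genomic clusters and markers of other cell types, 19 with at least 2 tested members, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Separation of the groups, the difference in spread and the shares of abundant miRNAs were tested over the 56 splits of 8 libraries into 5 and 3, two-sided except for the separation, which was one-sided. The smallest exact p this design can give is 0.0179. Groups, tests, lists and most alternatives were fixed before the data were examined.

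The rule for named miRNAs took the 12 largest changes per direction past the threshold, or the 4 smallest unadjusted p per direction where fewer than 4 passed. It also took the 10 most abundant miRNAs, the members of each list with the smallest p (the rule allowed up to 4), the miRNAs miR-18a, miR-19a, miR-181a, miR-21, miR-34c, miR-155 and miR-210, and the spike-in. Within that limit, 3 members per list were used at first, which gave 60 miRNAs, and this was lowered to 2 for length after the output was seen, which gave the 45 used here. miR-210 was above the floor in too few libraries to be tested.

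The model was tested on simulated data with the spread of the 193 miRNAs, 36 of them changed in each of 20 runs. It recovered 12.9% of log2 changes of 2, 54.2% of changes of 4 and 73.3% of changes of 6, with 0.95 false calls per run, and 0.15 calls per run without change. A list shifted by 2 was called in 100% of runs, and 0.05 lists per run were called without change, in data simulated with independent miRNAs.

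Alternatives covered the pseudocount (0.1 and 10), the filter, median centring, quantile normalisation, the trend, robust fitting, array weights, a fold minimum of 1.5, exact permutation per miRNA and leaving out each library. Alternatives chosen after the data were seen kept each locus separate, used limma-voom on recovered reads with median-of-ratios scaling, raised all values to a common floor of 8.50, or left out the 2 shallowest libraries. Separation without overlap was also counted after each of 4 rescalings, a check added after the data were seen. A count model was planned only for counts or for reads recovered at nearly every locus, and the values set to 1 kept the table from meeting that condition, so none was run. Thinning, chi-square tests and binomial intervals used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.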

Results

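The series asked which miRNAs differ in the vesicles shed by malignant and by normal canine mammary cells. Normalised values of miRNAs were compared between 5 CMT lines (CMT-27, CMT-28, CMT-12, CMT-47 and CMT-119) and 3 CMEC samples (CMEC1 to CMEC3). Of 452 miRNAs, 241 were above the floor of the table in at least 1 library and 105 in all 8. Recovered reads ranged from 81138 in CMT-12 to 1405893 in CMT-27.

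miR-21, an abundant miRNA widely described as oncogenic, was the leading miRNA of each of the 8 libraries. It made up 49.2% ± 14.5 of the summed value in CMT vesicles (SD, n = 5) and 37.4% ± 12.6 in CMEC vesicles (SD, n = 3; exact permutation p = 0.339). miR-148a, a miRNA abundant in milk, held 24.4% in CMEC2 and 25.0% in CMEC3, but 2.42% in CMEC1 and 3.08% ± 1.44 in CMT vesicles (SD, n = 5). The CMEC mean of miR-148a was 17.3% ± 12.9 (SD, n = 3; exact permutation p = 0.0714). miR-99a had 2.54% ± 1.07 in CMT vesicles (SD, n = 5) against 5.36% ± 1.20 in CMEC vesicles (SD, n = 3). These shares did not overlap between groups (exact permutation p = 0.0179, the smallest possible, and 0.179 after adjustment over the 10 miRNAs). Its deposited values did overlap, at 4514 to 22442 in the CMT lines and 11384 to 32409 in the CMEC samples (log2 difference -0.84, limma adjusted p = 0.717).

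miR-143, described in smooth muscle and fibroblasts, ranged from 0.0132% in CMT-27 and 0.244% in CMT-12 to 13.9% in CMT-47, and reached 17.8% in CMEC2 (exact permutation p = 0.286 between groups). miR-27b held 5.53% ± 4.13 in CMT (SD, n = 5) and 1.79% ± 0.885 in CMEC (SD, n = 3; exact permutation p = 0.214). let-7a, let-7b and let-7f, members of a family described as tumour-suppressive, each held 1.67% to 3.09% on average in either group. miR-140 and miR-30a reached 7.97% and 4.87% in CMEC1 and at most 0.142% in CMEC2 and CMEC3. None of these shares passed the threshold, for which at least 4 of the 10 would need the smallest possible p. The 10 miRNAs together held 47.5% in CMT-12 to 87.5% in CMEC3.

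**Figure D1:**
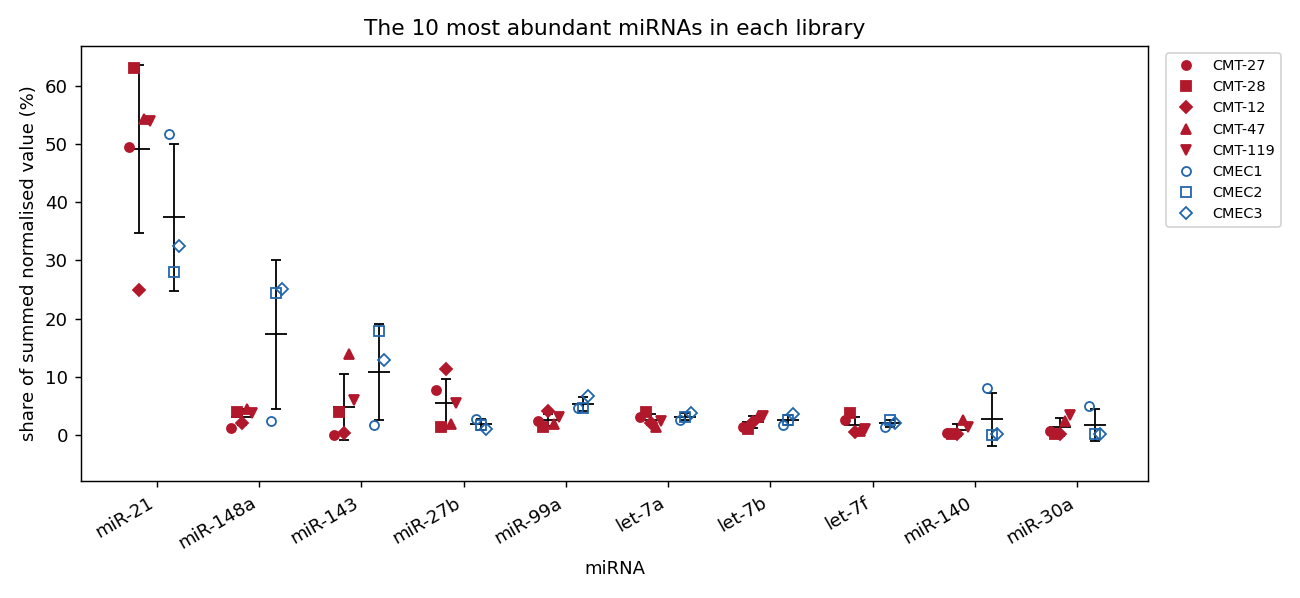
Share of the summed normalised value (%, linear axis) of the 10 most abundant miRNAs, with 1 point per library (filled, CMT; open, CMEC), horizontal bars for group means and error bars for SD. miR-21 lies between 24.9% and 63.1% in all libraries, and miR-148a is near 24.4% and 25.0% in CMEC2 and CMEC3 but 2.42% in CMEC1.

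The 4 smallest p-values in each direction belonged to miR-183, miR-182, miR-9 and miR-181b, higher in CMT vesicles, and to miR-504, miR-10a, miR-199 and miR-214, lower in CMT vesicles. miR-183 and miR-182, neighbours in a cluster active in sensory and epithelial cells, were 4.52 ± 1.30 and 4.22 ± 1.22 higher in CMT on the log2 scale (SE, 5 against 3 libraries). miR-9, known from neural development, was 4.81 ± 1.498 higher, and miR-181b, of a family that acts in lymphocyte development, was 3.11 ± 0.99 higher. On the lower side, miR-10a, encoded in a Hox cluster, was at -5.21 ± 1.47, miR-199 at -4.19 ± 1.61 and miR-214 at -2.79 ± 1.11. miR-504 was at the floor in all 5 CMT lines and at 5.67 to 27.7 in the CMEC samples. Its CMEC mean was 4.45-fold a floor of 3 reads averaged over the CMT libraries. That ratio is no bound for each line, since 3 reads were worth 6.96 in CMT-12. This is above miR-504 in CMEC1 (6.53) and in CMEC2 (5.67, which is 2 reads). CMEC3 carried the ratio, which was 2.04-fold without it and 3.86-fold to 6.65-fold without any other library.

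None of these differences passed the threshold. limma called 0 of 193 miRNAs, with a smallest adjusted p of 0.151 (miR-504, miR-10a, miR-183 and miR-182), 0.196 for miR-9 and miR-181b and 0.385 for miR-199 and miR-214. At an unadjusted p under 0.05 there were 21 miRNAs, 13 higher and 8 lower in CMT, where 9.65 would be expected by chance for independent miRNAs. Of the other splits of the same libraries into 5 and 3, 7 gave at least 21, and the highest gave 32. limma-voom on recovered reads called 0. Exact permutation per miRNA could call a miRNA only if at least 69 of the 193 had the smallest possible p, so its count of 0 decides nothing (14 had an unadjusted p under 0.05). With sample weights, 15 miRNAs passed (8 higher, 7 lower), and without CMEC1 6 passed: miR-183, miR-182 and miR-9 higher, and miR-10a, miR-214 and miR-383 lower, the last named after its values were seen. With each library left out, miR-183 ran from 3.15 to 6.55, miR-182 from 3.07 to 6.02, miR-9 from 3.73 to 6.75 and miR-214 from -4.41 to -1.89, and the largest differences of these were those without CMEC1.

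CMEC1 stood apart from the other normal samples for these miRNAs. miR-183 was at 1676 in CMEC1, against 14.2 in CMEC2 and 40.2 in CMEC3, and at 800.5 to 4496 in the CMT lines. miR-182 was at 2108 in CMEC1, against 70.8 and 34.7, and miR-9 at 251, against 2.83 and 4.16. miR-10a was at 163 in CMEC1, against 1700 and 4176. By contrast, miR-181b was lower in each of the 3 CMEC samples (53.8 to 81.6) than in any CMT line (250 to 1706), as was miR-181a (107 to 207 against 323 to 3048). Such separation without overlap held for 15 miRNAs higher and 3 lower in CMT, of 193, where chance gives 3.57%. These counts hold for the deposited scale only: they were 5 and 9 after median centring, 6 and 6 after subtraction of each library's median, 6 and 7 after quantile normalisation and 6 and 8 with voom. miR-181b stayed apart in all 4, and miR-181a only after subtraction of each library's median. Some separations as deposited rest on the floor or on single reads. For miR-1841 and miR-215 the lowest CMT value was 1.16 and the highest CMEC value 1.09, where 1 read in CMEC2 was worth 2.83. miR-676 was at the floor in CMT and at 1.09 in the lowest CMEC sample, and miR-16 parted at 76.52 against 76.50. The rescaled counts of lower miRNAs hold both miR-133a and miR-133c, whose values are identical.

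In canFam3, as the table gives them, miR-183 lies on chromosome 14 from 7068542 to 7068563 and miR-182 at 7072722 to 7072745 on the same strand. miR-10a lies on chromosome 9 from 24842212 to 24842233, miR-504 on chromosome X from 108693112 to 108693133 and miR-21 on chromosome 9 from 34340550 to 34340571. The host genes and exons of these loci were not analysed here. miR-9 has 3 loci, miR-199 has 3 and miR-181a and miR-181b have 2 each, and reads from such copies cannot be assigned to 1 locus. miR-133a and miR-133c had identical values, so their reads are shared.

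**Figure D2:**
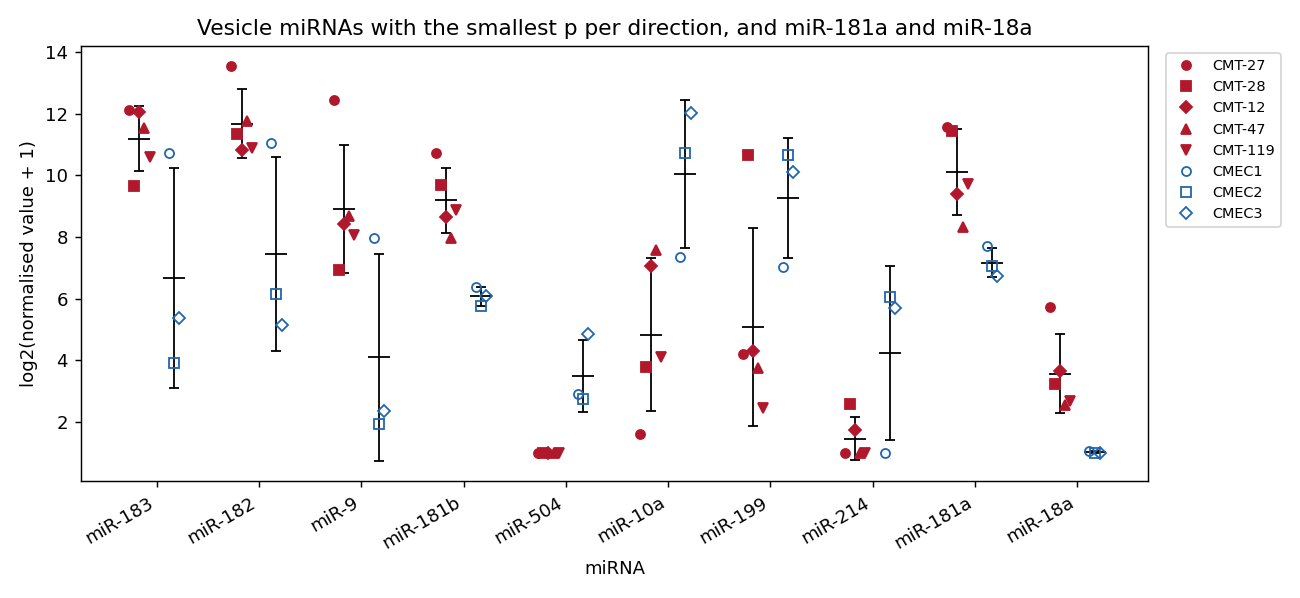
log2(normalised value + 1) of the 8 miRNAs with the smallest p (4 per direction) and of miR-181a and miR-18a, with 1 point per library (filled, CMT; open, CMEC), horizontal bars for group means and error bars for SD. miR-181a and miR-181b do not overlap between groups on this scale, whereas CMEC1 lies among the CMT lines for miR-183, miR-182 and miR-9.

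The direction of the whole profile depended on scaling. The median log2 difference of all 193 miRNAs was 0.75 as deposited, -0.35 after median centring, 0.13 after quantile normalisation and -0.33 with limma-voom on recovered reads. Of the miRNAs at an unadjusted p under 0.05, 61.9% were higher in CMT as deposited, 28.0% after median centring, 46.4% after quantile normalisation and 29.2% with voom. List values below are therefore given relative to the median of all tested miRNAs. Differences of single miRNAs are as deposited unless stated. After median centring, for example, miR-155 was at 1.19, miR-18a at 1.45, miR-19a at 0.66 and miR-34c at 0.70. On the lower side, miR-196b was then at -3.41 and miR-34a at -2.40. miR-21 was 0.69 ± 0.96 higher in CMT as deposited (limma adjusted p = 0.769), -0.41 after median centring and -0.27 with voom, and as deposited it ran from 0.20 without CMEC2 to 1.24 without CMT-12.

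Among the fixed lists, 4 of 19 passed camera's threshold at the preset correlation, and 0 with an estimated correlation, where the adjusted p was 0.582 for the epithelial, miR-181 and oncogenic lists and 0.386 for the mesenchymal list. Members are counted as above or below the median difference of all tested miRNAs, since 141 of 193 were higher in CMT as deposited. The other epithelial list holds the miR-183 cluster, miR-203 and miR-205. It was higher in CMT by a relative median of 2.47 (adjusted p of the list = 0.00889). In it, 5 of 5 members were above the median, among them miR-96 at 2.92 ± 1.46. These are not 5 separate results, since miR-183, miR-182 and miR-96 lie in 1 cluster. miR-203 exceeded its highest CMEC value (11.3) only in CMT-27 and CMT-12, with 7.73 in CMT-28, 2.78 in CMT-47 and 8.06 in CMT-119. miR-205 was at 473 in CMT-12 and at 1 to 15.2 in the other CMT lines, against 1 to 5.67 in CMEC. The miR-181 family was higher by 2.20 (adjusted p of the list = 0.00889), with 4 of 4 members above and miR-181a at 2.93 ± 1.00. The list of widely described oncogenic miRNAs was higher by 2.17, with 8 of 11 members above (adjusted p = 0.00857) and miR-21, miR-221 and miR-222 below. It holds miR-96, miR-182 and miR-183, as the epithelial list does, and miR-155, at 2.29 ± 1.27 (limma adjusted p = 0.537) and at 1.32 without CMEC1. Markers of mesenchymal and smooth-muscle-like cells were lower by a relative median of -2.85, with 6 of 6 members below (adjusted p = 0.000861), among them miR-143 at -2.52 ± 1.72. The relative median of the list was -1.52 without CMT-27 and -3.85 without CMEC1, and miR-143 ran from -1.23 without CMT-27 to -3.63 without CMT-47.

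The relative medians of these 4 lists kept their sign after quantile normalisation and with voom, and median centring cannot move them. fry called 0 lists in either direction and 0 in its mixed test, and 1 list had an unadjusted p under 0.05 with an estimated correlation. Adjusted over the list alone, 2 members passed in the epithelial list, 2 in the miR-181 family, 3 in the oncogenic list and 0 in the mesenchymal list, against 0 over all miRNAs tested. By the same adjustment, 1 member passed in the miR-10 list and 1 in the endothelial, muscle, liver and neural list, which were not called. CMEC1 was the normal sample nearest to the CMT lines for the epithelial, oncogenic and mesenchymal lists. Its mean for the epithelial list was 1.51 above its library median, against -0.13 in CMEC2 and -0.41 in CMEC3. For the oncogenic list it was 3.41 above, against 2.13 and 2.55. Its mesenchymal list was 2.47 above the library median, against 5.40 and 5.16. CMT-28 had 4.29 for that list, with miR-199 at 1616, and CMT-27 had -2.38.

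**Figure D3:**
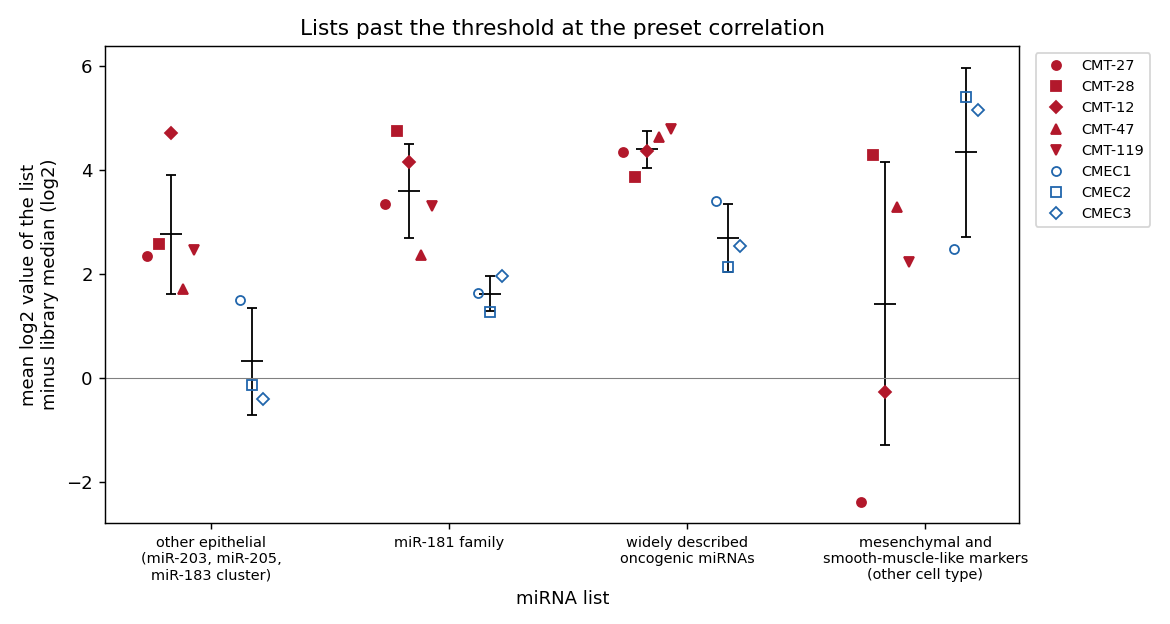
Mean log2 value of each list past the preset-correlation threshold, minus the library median (log2), with 1 point per library (filled, CMT; open, CMEC), horizontal bars for group means and error bars for SD. The miR-181, epithelial and oncogenic lists do not overlap between groups, and the mesenchymal list spans -2.38 to 4.29 among CMT lines.

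The other lists did not pass. The clusters miR-17~92, miR-106b~25 and miR-106a~363, described as promoting proliferation, had 9 of 11 members above the median difference of all tested miRNAs, with a relative median of 1.07 (adjusted p = 0.0619, and 0.784 with an estimated correlation). This list passed camera's preset-correlation threshold in 8 of 21 alternatives. Over these its camera adjusted p ran from 0.000173 with no filter to 0.312 with miRNAs above the floor in all libraries. With no filter, camera used all 452 miRNAs, of which only 241 were above the floor in any library. The rest had a difference of 0, so that p has another comparison set than the main fit. Among the members of these clusters, miR-18a was at 4.86 to 52.6 in the CMT lines and at 1 to 1.09 in CMEC. This is a log2 difference of 2.55 ± 0.95 (limma adjusted p = 0.385). Its CMEC values were the floor or, in CMEC1, 1 read, and 1 read in CMEC2 was worth 2.83. miR-106b was at 3.24 ± 1.36 and miR-19a at 1.76 ± 1.21 (1.10 without CMT-27). The list of miR-10, miR-99, miR-100, miR-125 and miR-196 had a relative median of -0.27 (adjusted p = 0.113), with miR-196b at -2.31 ± 0.98. The let-7 family had -0.77 (adjusted p = 0.273), the miR-23, miR-24 and miR-27 clusters 0.62 (0.346), blood cell markers -1.17 (0.353) and endothelial, muscle, liver and neural markers -0.44 (0.426), as camera adjusted p.

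The miR-29 family had a relative median of 0.85 and the miRNAs described to target estrogen receptor alpha 0.80 (both adjusted p = 0.470). The miR-200 family had 1.60, miR-221 and miR-222 had -0.81, the miR-15 and miR-16 family had 0.76 and the imprinted DLK1-DIO3 cluster had -0.14 (all adjusted p = 0.613). With each library left out, the miR-29 family ran from 0.33 to 1.13 and the estrogen receptor list from 0.46 to 1.02. miR-221 and miR-222 ran from -1.40 to -0.32 and the miR-15 and miR-16 family from 0.15 to 0.84. The miR-200 family ran from 0.71 to 2.47 in the fits that could test it. Without CMT-27, CMT-12 or CMEC2 it was not tested, since miR-200a was above the floor only in these 3 libraries. Its other tested member, miR-200c, had a log2 difference of 0.47 without CMT-27 and of 3.67 without CMT-28. The p53-responsive list had 0.41 (adjusted p = 0.716), with miR-34c, a p53 target, at 1.38 to 23.6 in CMT lines and at most 1.09 in CMEC (1.80 ± 0.85, limma adjusted p = 0.455), where 1 read in CMEC2 was worth 2.83, and miR-34a at -1.31 ± 0.70. The miR-30 family had 0.12 (adjusted p = 0.893) and milk-abundant miRNAs 0.22 (adjusted p = 0.995), and camera's direction for both was down, against the sign of these medians.

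The libraries of a group did not resemble one another more than those of the other group by a test. The mean distance between groups exceeded that within groups by 1.14 log2 units (Euclidean over 193 miRNAs; exact permutation p = 0.339, one-sided, 56 splits). This difference was 3.28 without CMEC1, -1.66 without CMEC2 and -1.35 without CMEC3, and 1.20 (without CMT-119) to 3.18 (without CMT-28) with a CMT line left out. CMT-47 and CMT-119 were the closest pair, with a Spearman correlation across miRNAs of 0.941, and CMEC2 and CMEC3 had 0.875. CMEC1 had 0.902 with CMT-47, 0.758 with CMEC2 and 0.803 with CMEC3. Correlations are across miRNAs, which are not independent replicates.

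**Figure D4:**
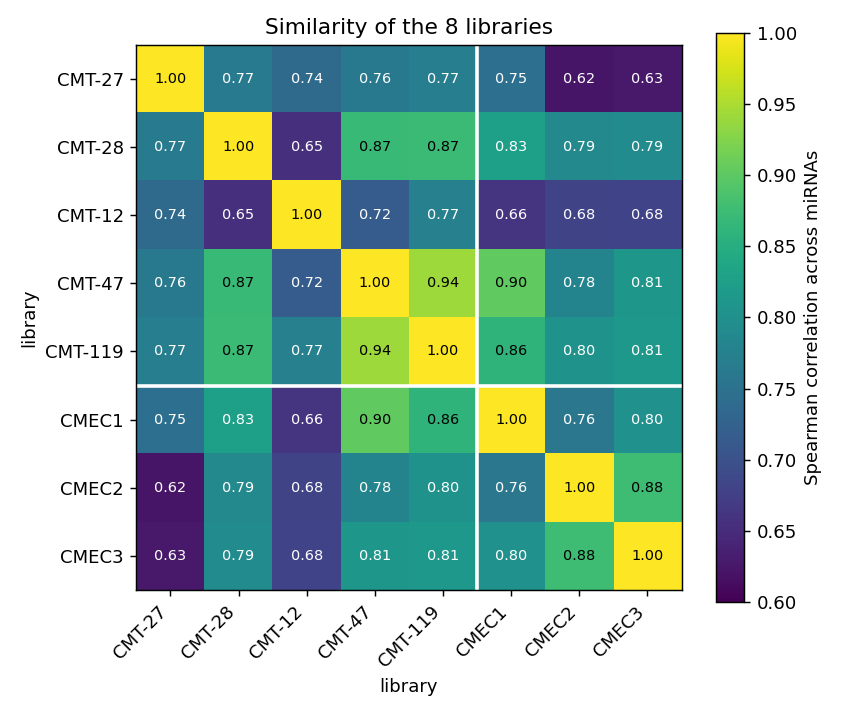
Spearman correlation across 193 miRNAs for each pair of libraries (colour and printed value; both axes list the libraries, and white lines part CMT from CMEC). CMEC1 has a higher value with CMT-47 (0.902) than with CMEC2 (0.758) or CMEC3 (0.803).

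The spread among the tumour lines was not shown to differ from that among the normal samples. The median SD per miRNA was 1.49 among the 5 CMT lines and 1.00 among the 3 CMEC samples, a difference of 0.49 (two-sided exact permutation p = 0.857). Without CMT-27 the difference was -0.0060, and without CMEC1 0.89. CMT-27 and CMT-12 carried most of the miR-200 family signal: miR-200c, which holds cells in an epithelial state, was at 13903 in CMT-27 and 2022 in CMT-12, and at 1 to 8.06 in the other CMT lines and 5.44 to 25.5 in CMEC.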

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

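In the 5 CMT lines, 50 results were screened for a library far from the others, and 3 were found, where chance alone gives about 1 in 20. The 3 CMEC samples were too few for this screen. miR-199 was far higher in CMT-28, at a log2 value of 10.66, than in the next line, at 4.29. miR-451, a red blood cell miRNA, was at 5.42 in CMT-12 on the log2 scale and at 1.48 in the next line.

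The median log2 value of CMT-27 was 6.93, against 4.73 in the next line. Both tests of this pattern were set before their results were seen. With each library thinned to 81138 reads, CMT-27 had 156 miRNAs detected in the lowest of 100 thinnings and 166 on average, within the range of the other libraries, whose highest was CMT-12 with 168. Its median per miRNA was 8 reads in the lowest thinning and 9.57 on average, against 11 in CMT-12. In the rest it was at most 4.75 on average and at most 6 in any thinning. Greater depth and the deposited scaling factor could thus each account for its place above CMT-12. Neither accounts for its higher median than in the rest, which stayed with equal reads. No biological explanation was tested. The step of CMT-27 times its median-of-ratios factor was 4.503, against at most 1.20 elsewhere.

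For the count of called miRNAs between CMT and CMEC, the comparison with other splits decides nothing: the real split gave 0, so all 56 of the 56 splits had to give at least as many, and the highest of the others gave 4. Chance was not excluded for the count of lists: the real split gave 4, 6 of 56 splits gave at least 4, and the highest of the others also gave 4.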

How the results depend on the processing

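The alternatives voom on recovered reads, common floor, every locus separate and without CMT-12 and CMEC2 were chosen after the data were seen. The count of called miRNAs was 0 except with array weights (15) and without CMEC1, and leaving out each library gave 0 to 6. The 0 by exact permutation decides nothing, since 69 of 193 miRNAs would have to share the smallest possible p. The lowest adjusted p over the other settings was 0.0625 with voom. The array weights were lowest for CMT-27 (0.176) and highest for CMT-119 (3.36). The count of lists was 7 with no filter, 7 without CMT-12 and CMEC2, 0 with an estimated correlation and 0 by fry, and 3 to 6 with each library left out, against 4. With no filter, lists were compared with a set that held miRNAs at the floor in all libraries, whose difference is 0. The miR-181 list was no longer called without CMEC1 (adjusted p = 0.0607) or with only miRNAs above the floor in all libraries (0.0510). Its relative median was 1.99 and 2.01 in these settings, against 2.20 in the main fit. Gained calls at the preset correlation were those of the miR-17~92 list (with no filter, median centring, no trend, voom, without CMT-12 and CMEC2, and without CMT-27, CMT-12 or CMEC2), the miR-10 list in 4 alternatives, the miR-23, miR-24 and miR-27 clusters with no filter and the DLK1-DIO3 cluster without CMT-12 and CMEC2. Separation ran from -1.66 without CMEC2 to 3.28 without CMEC1 with each library left out and was -1.02 without CMT-12 and CMEC2. The difference in spread ran from -0.0060 to 0.89, and the share of miR-21 from 42.2% to 47.6%. Named miRNAs kept direction and side of the threshold in 819 comparisons with an alternative, were newly called in 16 and turned in 34. List medians did so in 347, 14 and 24, and 2 calls were lost. List medians were first taken without subtracting the median of all miRNAs, which turned 32, and this was changed after the output was seen because camera compares a list with the other miRNAs. With 3 members named per list, 41 named values turned. No paired analysis was possible because the numbers of CMT lines are arbitrary and pair with no CMEC sample. The planned DESeq2 alternative was not run, since the table gives no whole reads at the floor. The low number of recovered reads limited low miRNAs in CMT-12 and CMEC2, where 1 read was worth 2.32 and 2.83.

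The following values turned direction. Median centring lowered all differences by the same amount, which took their median from 0.75 to -0.35, so small positive differences had to turn. The cause of the other turns was not tested. As log2 differences after median centring, miR-21 was at -0.41, miR-140 at -0.20, miR-30a at -0.23, let-7g at -0.40 and miR-221 at -0.59. With quantile normalization miR-140 was at -0.088, miR-30a at -0.32, let-7g at -0.12 and miR-221 at -0.35. With voom on recovered reads miR-21 was at -0.27, miR-140 at -0.37, miR-30a at -0.26, let-7g at -0.18, miR-221 at -0.55, miR-495 at -0.13 and miR-543 at -0.34. With array weights let-7b was at 0.29 and miR-200c at -0.73. Without CMT-12 and CMEC2 let-7a was at 0.061, let-7f at 0.21, miR-140 at -0.013 and miR-543 at -0.25. With each library left out, let-7a ran from -0.37 to 0.36, let-7b from -0.36 to 0.41, let-7f from -0.87 to 0.33, miR-140 from -0.79 to 3.39, miR-221 from -0.36 to 1.85 and miR-30a from -0.19 to 2.79.

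For relative list medians, the p53-responsive list was at -0.17 with pseudocount 10. With no filter the DLK1-DIO3 cluster was at 0.18 and the endothelial, muscle, liver and neural list at 0.15. Above the floor in all 8 samples, the miR-30 family was at -0.050, the endothelial, muscle, liver and neural list at 1.499 and the milk list at -0.24. With quantile normalization the miR-30 family was at -0.45, and with every locus separate at -0.78. With array weights the miR-200 family was at -0.81, miR-221 and miR-222 at 0.25 and the milk list at -0.39. With a common floor the miR-15 and miR-16 family was at -0.20, the endothelial, muscle, liver and neural list at 1.47 and the milk list at -0.049. With each library left out, the DLK1-DIO3 cluster ran from -0.69 to 0.12, blood cell markers from -2.08 to 0.53, the miR-10 list from -0.90 to 0.27, the miR-30 family from -0.65 to 0.80, the p53-responsive list from -0.060 to 0.72 and the milk list from -0.087 to 0.63.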

Other observations

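The tests of carried-over reads, exchanged labels, few reads and blood RNA below were chosen after the results they bear on were seen. miR-206 and miR-1 were chosen for description after their values were seen. miR-206, known from skeletal muscle, was at 2570 in CMEC2 and 298 in CMEC3, and at the floor in the other 6 libraries, so it was not tested. miR-1, its relative, was at 1060 and 805 in CMEC2 and CMEC3, at 182 in CMEC1 and at 25.1 to 352 in the CMT lines. miR-133a, another muscle miRNA, was at 8.70 in CMEC1 and, with 2 reads each, at 5.67 in CMEC2 and 2.77 in CMEC3, and at 1 to 4.16 in the CMT lines. It was lower in each CMT line than in any CMEC sample after each of 4 rescalings, but not as deposited. That order shows no separation, since it rests on few reads and on the floor: 1 read in CMT-12 was worth 2.32. miR-499 was at 92.5, 17.0 and 18.0 in CMEC1 to CMEC3 and at 40.2 to 251 in the CMT lines. Unlike miR-206 and miR-1, it was thus lower in CMEC2 and CMEC3 than in the other libraries. Of the miR-200 family, a mark of epithelial cells, miR-429 and miR-200b were at the floor in all 3 CMEC samples and in CMT-28, CMT-47 and CMT-119. miR-429 was at 1127 in CMT-27 and 269 in CMT-12, and miR-205, a basal epithelial miRNA, was at 473 in CMT-12.

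CMEC1 was nearer to CMT-47 than to CMEC2 and CMEC3, which depth did not account for: with equal reads, the correlation with CMT-47 exceeded the higher of the other two by 0.0348 in the lowest of 100 thinnings and by 0.0883 on average, a test set beforehand. An exchange of labels between groups found no partner, since 0 CMT libraries had CMEC2 or CMEC3 as their nearest library. This does not exclude an exchange, because an exchanged normal culture need not be nearest to CMEC2 or CMEC3. For reads carried over from CMT-47, the rule used gave no decision. At the share that miR-182, miR-183 and miR-9 would need, 2 of its 36 abundant miRNAs were below 0.5 of the level brought. This count was 4 to 14 for the other lines. A carried share cannot exceed the share that any single miRNA allows. Of the 36, 12 were below the needed level, and miR-122 allowed a share of 0.00383 where 0.593 was needed. miR-143 was at 7204 in CMEC1 and at 100702 in CMT-47. These values argue against carry-over from CMT-47 at the needed share. An earlier form of this test was the ratio of the 10th percentile of allowed shares to the needed share, with a bound of 0.5. It gave 0.584 for CMT-47 and also no decision. A single wrong label, or normal cultures that differ, was not tested.

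miR-122, a liver miRNA also found in serum, made up 9.76% of reads in CMT-12 (95% exact binomial interval 9.55% to 9.96%) and at most 0.277% elsewhere. A low number of reads alone did not account for it, since CMEC2, about as shallow, had 0.00233% (0.000282% to 0.00841%), under the median of 0.0231%. Blood or serum RNA may have contributed: 3 of the 4 tested blood cell miRNAs (miR-451, miR-486 and miR-142) had their highest share in CMT-12. These were low, at most 0.0740% of reads, were second highest in CMEC2, and the medium is described as serum-free. miR-122 did not follow these 3 miRNAs across the other libraries. It was above the median in CMT-119 (0.277%) and CMT-47 (0.235%). In these 2 lines miR-142 had 0%, miR-451 at most 0.00037% and miR-486 at most 0.00518%. A biological difference of CMT-12 was not tested and stays open.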
